A study of Mus musculus with 8 samples.

How the data were processed

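The study profiled total RNA of 8 primary cultures of mouse aortic smooth muscle cells, 4 with angiotensin II and 4 with angiotensin II and cyclosporin A, which the labels describe as independent cultures. Per the labels, RNA was amplified into Cy3-labelled RNA with T7 polymerase, so each array has 1 colour. Per the file headers, the arrays are of Agilent design 014868 and were quantified with Agilent Feature Extraction 9.5.3.1 under protocol GE1-v5_95_Feb07. The files deposited by the authors give for each spot an intensity on a linear scale, namely the processed signal (background-subtracted and adjusted by that software), the mean signal and the local background, with marks for outlier, saturated and well-above-background spots. The authors also deposited a table of log2 values of the same arrays. Its columns rank the probes as their own array does (Spearman rho of at least 1.00 to 2 decimals), have a median of 3.01 in each array and differ by at most 0.00185 between arrays after sorting, as quantile normalization leaves them. Its method and the constant that sets its scale stay unknown. It was used as an alternative.

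The values analysed were log2 of the processed signal minus the 75th percentile of each array. Control spots and outlier spots were left out, no spot was saturated, and spots of the same probe were averaged. Of 41174 probes, 22951 were named through their accession in a RefSeq gene table of assembly GRCm38.p6, 6659 carried a current symbol already, and 11564 kept the name in the files. Of all probes, 17101 were above background on no array. Probes above background on at least 4 of the 8 arrays were kept without regard to the groups, which left 19529, and each gene was represented by its probe with the highest mean, giving 14881 genes and transcripts, 11946 of them with a current symbol. The probe coordinates are those of the files, in build mm7. Where a probe was below background in every array of a group, the bound sets the brighter group's mean against the dimmer group's mean of, per array, the higher of the probe's own value and the lowest signal that was above background.

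Differences were tested two-sided with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The fit on the 2 groups alone was chosen before the data were examined, together with the alternatives, the 23 gene lists and the rule for named genes. Lists with at least 5 measured members (22) were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists. The rule named Rcan1, the NFAT and calcineurin subunit genes, Ppia, Agtr1a and Ptgs2 whatever they showed, up to 12 rises and 12 falls past the threshold or else the 5 of each direction with the smallest p, and up to 4 members per list past the threshold or else the 2 with the smallest p. The rises and falls were picked from genes with a current symbol other than a RIKEN, Gm or LOC name. Acta2, Tagln, Il6, Ccl2, Nr4a2, Myc, Egr4 and Dusp2 were named after their values were seen, as were the further genes in the closing observations.

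The labels number the cultures 1 to 4 in each group, and per the file headers arrays with the same number share a slide and a scan, 4 slides in all, so a block by replicate and a block by slide are the same fit. Deviations from the group means correlated at 0.70 to 0.86 between arrays of the same number and at -0.76 to 0.26 between other arrays, so the numbers were taken to pair the arrays. Number and slide cannot be separated as the source of the pairing. The median residual SD over genes was 0.437 without the block, on 6 residual degrees of freedom, and 0.184 with it, on 3.

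Both fits were tested on simulated data for AngII+CsA against AngII with the 14857 genes complete on all arrays, using their means, replicate effects and moderated residual SDs, in 10 draws with 200 changed genes of 4 sizes. Noise was drawn independently for each gene. Without the block, 0% of changes of 1 log2, 16% of those of 1.5 and 55.8% of those of 2 were recovered. With the block, the shares were 12.6% for 0.5, 87.6% for 1, 98.6% for 1.5 and 99.8% for 2. In these draws a mean of 0 calls without the block and 9.4 with it were false, and with no simulated change the mean number of calls was 0 and 0.4 (at most 0 and 2). The shares recovered hold for the simulated settings and need not hold for the measured genes. Among those, 27 were lower and 4 higher by more than 1 log2, and 4 genes passed with the block. A shift of -0.5 in the calcineurin-NFAT targets was called by camera in 10 of 10 draws with either fit, beside a mean of 0.7 and 0.9 other lists. Other settings covered background correction, scaling, the filter on dim probes, outlier spots, the choice of probe, the variance model, the authors' table and leaving out each array.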

Results

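Gene expression was measured in primary vascular smooth muscle cells from the aortas of C57BL/6 mice, the contractile cells of the arterial wall, on 8 one-colour arrays in 2 groups of 4 independent cultures. Cultures of the AngII group received 1 µM angiotensin II, the peptide hormone that contracts arteries and drives smooth muscle remodelling. Cultures of the AngII+CsA group received the same dose together with 200 ng/ml cyclosporin A, a drug that binds cyclophilin and inhibits the calcium-dependent phosphatase calcineurin. The comparison asked which transcripts of angiotensin-treated cells are sensitive to cyclosporin. Cells without angiotensin were not analysed here, so the response to angiotensin itself was not measured. Between 42.8% and 51.7% of the 43379 spots per array were well above background, and 14881 genes and unnamed transcripts were tested. The number of arrays limits the precision of every value.

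The arrays grouped by replicate number and not by treatment. The first principal component held 53.3% of the variance and the second 26.5%, and both arrays of replicate 1 lay apart from the other 6 on the first. Arrays with the same replicate number shared a slide, so a fit with the replicate number as a block is given beside the fit on the groups alone wherever it changes a call.

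**Figure D1:**
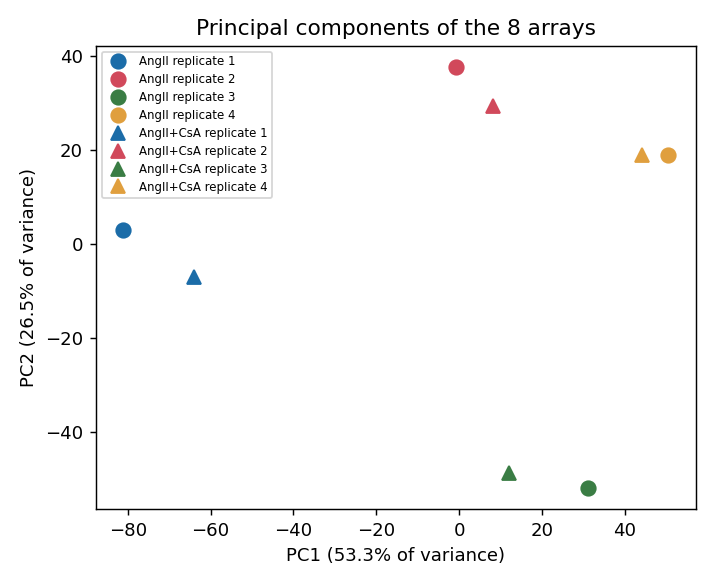
Principal components of the 14857 tested genes and transcripts with a value on all arrays, with each array as a point coloured by replicate number; circles are AngII and triangles AngII+CsA. The axes are component scores with their share of the variance, 53.3% and 26.5%, and arrays of the same replicate number lie next to each other.

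Rcan1, the feedback regulator of calcineurin whose inducible promoter is driven by NFAT, showed the largest cyclosporin effect of the genes that passed a test. Its log2 signal relative to the array's 75th percentile was 5.01 ± 0.61 (SD, n = 4) with AngII and 2.75 ± 0.69 (SD, n = 4) with AngII+CsA, a 4.79-fold lower level. The difference of -2.26 had a 95% interval of -2.56 to -1.96 with the replicate block, and the within-slide differences were -2.39, -2.12, -2.01 and -2.52. A second Rcan1 probe gave -1.51. Serpinb1a, an inhibitor of neutrophil serine proteases, went from 4.83 ± 0.31 to 3.52 ± 0.42 (SD, n = 4 each), a 2.47-fold lower level. Probes for its paralogs Serpinb1c and Serpinb1b differed by -1.57 and -1.34. These genes are close paralogs, and the other probe of Serpinb1c and of Serpinb1b was above background on 0 and 1 of the 8 arrays, so the values of both paralogs are uncertain. With the block under normexp background correction they were -1.02 and -0.84.

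With the replicate block, these 4 genes fell in AngII+CsA by limma with Benjamini-Hochberg adjustment, each in 4 of 4 pairs. The adjusted p was 0.0131 for Rcan1 and for Serpinb1c, 0.0462 for Serpinb1a and 0.049 for Serpinb1b, and 0 genes rose. In the fit on the groups alone 0 genes passed, with a smallest adjusted p of 0.9999, although Rcan1 and Serpinb1a ranked 1 and 2 of all genes. That fit gave 42 genes at an unadjusted p under 0.05, 37 lower and 5 higher. The 744 that uniform p-values give is no measure for it, because the replicate differences stay in its residual. In that fit the other splits of the arrays that part every pair gave 19 to 30. With the real split these are 8, too few for a share under 0.05. With the block there were 790, and 4048 under normexp background correction, for which no splits were run. The other splits of the arrays that part every pair gave 270 to 942 with the block, so 790 lies within their range. All 4 Rcan1 values with AngII+CsA lay below all 4 with AngII. The exact two-sided permutation p was 0.0286, the smallest that 4 against 4 arrays can give, but that test ignores the pairing. Sign flips over the 4 pairs, which keep it, gave a two-sided p of 0.125 and cannot go lower. The 4 blocked calls were lost when any 1 of the 4 pairs was left out, with an adjusted p for Rcan1 of 0.056 to 0.285, and 0 genes were called with no filter on dim probes. The Serpinb1b call was also lost with the block under normexp background correction (adjusted p = 0.0692), with outlier spots kept (0.0514) and with the authors' table (0.0539), where that of Serpinb1a was lost too (0.0539).

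**Figure D2:**
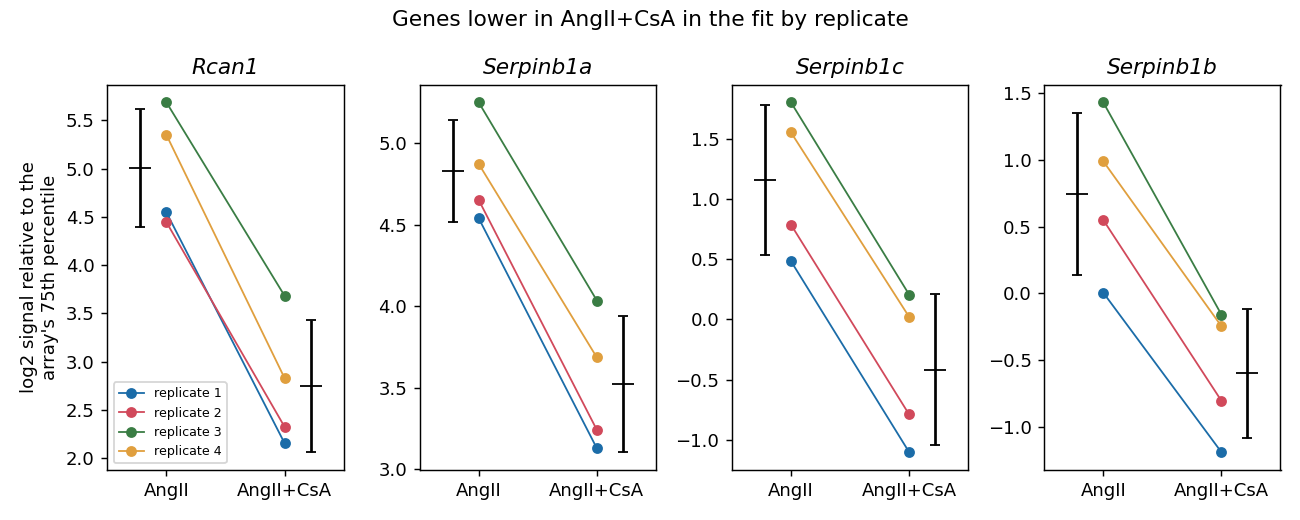
Log2 signal relative to the array's 75th percentile for Rcan1, Serpinb1a, Serpinb1c and Serpinb1b in AngII and AngII+CsA; points are arrays, lines join arrays of the same replicate number, and black bars are the mean and SD of 4 arrays. The axes differ between panels and do not start at 0. Within the 4 pairs the Rcan1 differences lay between -2.52 and -2.01.

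The Rcan1 probe lies on chromosome 16 from 92445136 to 92445195 in the mm7 build of the array annotation. The Serpinb1 probes lie together on chromosome 13, that of Serpinb1a from 32208400 to 32208459, that of Serpinb1c from 32249890 to 32251739, a span longer than the 60-base probe, and that of Serpinb1b from 32456903 to 32456962. Whether these positions are in an exon or a UTR was not looked up, because no annotation of that build was used here.

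Among the other genes that were lower, the smallest p on the groups alone belonged to Nkd2, an antagonist of Wnt signalling, 1.99-fold lower (4 of 4 pairs lower, adjusted p = 0.173 by limma with the block). It passed with the replicate as a random block (adjusted p = 0.00767) and with the block under the stricter filter on dim probes, where 5 genes passed. The other Nkd2 probe was above background on 1 of 4 AngII arrays and 0 of 4 AngII+CsA arrays, so the Nkd2 value rests on 1 probe. Among genes with a current symbol other than a RIKEN, Gm or LOC name, the 5 rises with the smallest p on the groups alone were those of Uba6 (0.56), Rasgef1a (0.74), Dapl1 (0.55), Kif5c (0.60) and Ucn2 (1.01) in log2. None passed either fit. Rasgef1a and Dapl1 were above background on 3 of 4 AngII arrays and 4 of 4 AngII+CsA arrays and Ucn2 on 1 and 3, so these sizes rest in part on signals at background. Over all genes the differences were small, with 97.3% within 0.5 log2 and a median of -0.03. In total 27 genes were lower and 4 higher by more than 1 log2.

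Genes known as targets of calcineurin and NFAT shifted down as a group. Of the 20 measured members, 16 had negative differences, with a median of -0.22 and within-slide medians of -0.23, -0.10, -0.14 and -0.41. The list fell by limma's camera test with its preset correlation, at an adjusted p of 0.000428 on the groups alone and 0.000643 with the block, but the adjusted p was 0.248 and 0.435 with an estimated correlation, and 0.775 and 0.0709 by fry. The correlation estimated for this list was 0.0353 on the groups alone and -0.00371 with the block. The latter is below the preset 0.01, so a higher correlation does not account for the loss with the block. That loss is therefore no evidence that the members are correlated. The endothelial markers had a similar median, -0.21, with 8 of 9 negative, but at dimmer signals (median level with AngII -2.34, against 3.22 for the targets). Adjusted over the list alone, 1 member fell on the groups alone (Rcan1) and 2 fell with the block (Rcan1 and Vcam1); over all genes tested the counts were 0 and 1. Vcam1, the adhesion molecule that binds leukocytes, fell by 0.67 (adjusted p = 0.0248 over the list alone by limma with the block, 4 of 4 pairs). Values for members that did not pass were -0.65 for the nuclear receptor Nr4a2, -0.58 for Il6, -0.50 for the monocyte chemokine Ccl2 and -0.36 for the protease Adamts1, each lower in 4 of 4 pairs, and 0.26 for Myc.

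Rcan1 weighed on this call. Without it the median was -0.22 and the adjusted p by camera was 0.0626 on the groups alone and 0.0194 with the block, but 0.594 and 0.573 with an estimated correlation and 0.987 and 0.213 by fry. The call on the groups alone was also lost without AngII replicate 2 (adjusted p = 0.235), without AngII+CsA replicate 4 (0.0504), with normexp background correction (0.104) and with no filter on dim probes (0.1), in a range of 2.74e-06 to 0.235 over the settings with the preset correlation. Ptgs2, the inducible cyclooxygenase, was not tested. Its brighter probe was above background on 2 of 4 AngII arrays and 0 of 4 AngII+CsA arrays, with a bound of 1.13-fold higher with AngII. That bound rests in part on AngII signals at background, so it is not a strict minimum. The other Ptgs2 probe was above background on 0 arrays of either group and differed by -0.15.

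**Figure D3:**
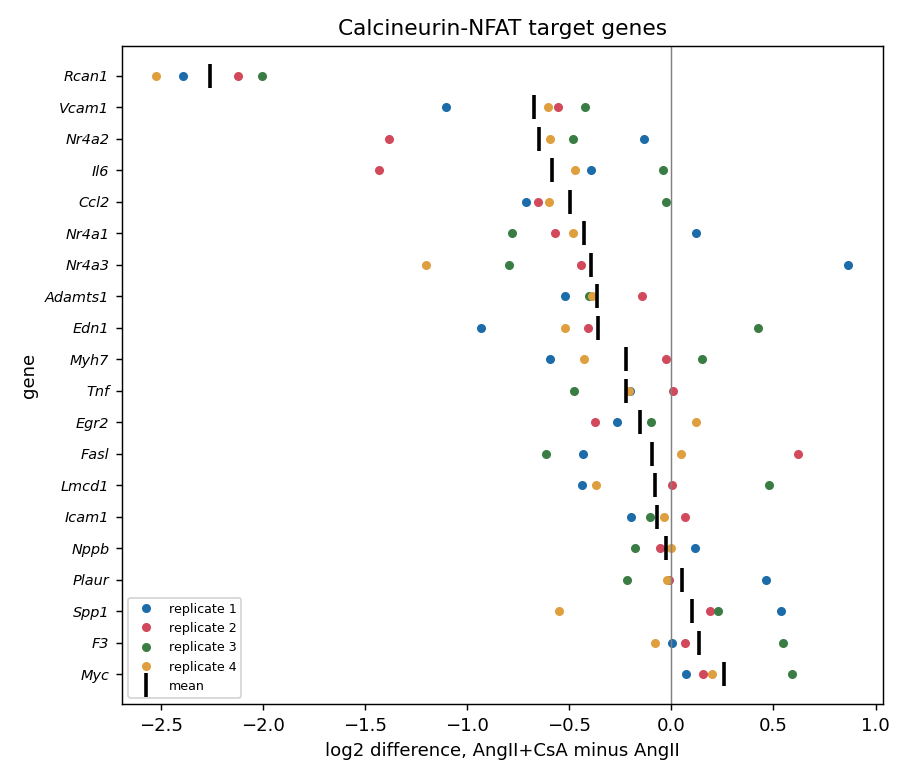
Log2 difference between AngII+CsA and AngII for the 20 measured calcineurin-NFAT target genes; points are the 4 replicate pairs and black ticks their mean. Rcan1 lies at -2.26, apart from the other members, and 16 of the 20 means are negative.

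Transcripts of the calcineurin-NFAT machinery itself did not pass as a list. The list of 19 measured components had 11 positive and 8 negative differences, with a median of 0.02 (adjusted p = 0.516 by camera). The catalytic subunits Ppp3ca and Ppp3cb differed by 0.22 and 0.00 and the regulatory subunit Ppp3r1 by 0.30. Nfatc2, Nfatc3 and Nfatc4 differed by 0.02, -0.03 and -0.11, while Nfatc1 was above background on 1 of 4 AngII arrays and 0 of 4 AngII+CsA arrays and was not tested. Ppia, which encodes cyclophilin A, differed by 0.02, and Agtr1a, the main angiotensin receptor of vascular muscle, by 0.08. None of the tested ones passed either fit.

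The contractile genes of smooth muscle did not shift as a list, with 12 positive and 8 negative differences among 20 members (adjusted p = 0.516 by camera). Cnn1, the actin-binding protein calponin 1, was the exception among them. Its log2 signal was 7.27 ± 0.96 with AngII and 5.56 ± 1.62 with AngII+CsA (SD, n = 4 each), lower in 4 of 4 pairs. Cnn1 fell by 1.71 adjusted over the list alone with the block (limma, adjusted p = 0.00678), but not over all genes tested (adjusted p = 0.459 with the block). Myh11, the smooth muscle myosin heavy chain, differed by 0.33, and Acta2 and Tagln by 0.01 and -0.02.

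Immediate early genes, the fast transcriptional responders to growth signals, went both ways, with 18 positive and 12 negative differences among 30 members and a median of 0.05 (adjusted p = 0.903 by camera). Adjusted over the list alone with the block, 1 member fell, the phosphatase gene Dusp2 by 0.84 (limma, adjusted p = 0.0224), and over all genes tested 0 did. With the block and no filter on dim probes the list passed camera (adjusted p = 0.0476, median 0.05). That call used the preset correlation. With the filter, camera with an estimated correlation gave an adjusted p of 0.949 (0.573 with the block). The preset did not pass there either, so these values do not test the call. Btg2 differed by -0.55 and Srf by -0.34. Among 22 inflammatory cytokines and chemokines the median was -0.06 (adjusted p = 0.574 by camera). Vcam1 and the chemokine gene Ccl7, at -0.60, fell when adjusted over the list alone with the block (limma, adjusted p = 0.033 each), and 0 members did over all genes tested. Of 10 interferon response genes, 7 had positive differences (median 0.05, adjusted p = 0.189 by camera), and Usp18, which restrains interferon signalling, rose by 0.54 adjusted over the list alone with the block (limma, adjusted p = 0.0439, 4 of 4 pairs), but not over all genes tested (adjusted p = 0.885 with the block). The interferon list passed camera with no filter on dim probes (median 0.03, adjusted p = 0.0146, and 0.0476 with the block), without AngII replicate 3 (median 0.28, adjusted p = 0.00567) and with the block without replicate 3 (median 0.13, adjusted p = 0.028). These calls used the preset correlation of 0.01. With all arrays and the filter, the correlation estimated for this list was 0.362 (adjusted p = 0.838 by camera). With the block it was 0.299 (adjusted p = 0.573). The list did not pass there with the preset correlation either, so these values do not test the calls. No estimated correlation is reported for the settings of the calls. Of 16 angiotensin receptors and G-protein regulators, 12 had negative differences (median -0.07, adjusted p = 0.189 by camera, and 0.0248 with the block without replicate 1 at a median of -0.14). Camera with an estimated correlation gave this list an adjusted p of 0.594 with all arrays (0.573 with the block). With all arrays the preset correlation did not pass either. The small GTPase gene Gem fell by 0.93 adjusted over the list alone with the block (limma, adjusted p = 0.0414), but not over all genes tested (adjusted p = 0.885 with the block). Gem was above background on 3 of 4 AngII arrays and 1 of 4 AngII+CsA arrays, so the size of this fall is uncertain. On the groups alone none of Vcam1, Cnn1, Dusp2, Ccl7, Usp18 and Gem passed. The adjustment over a list alone does not correct for the number of lists, and how many such calls chance gives was not computed.

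Lists for tissue remodelling and growth did not pass camera and had 0 members past either adjustment. The medians were 0.04 for 26 matrix and fibrosis genes, 0.05 for 17 matrix proteases and inhibitors, -0.09 for 22 cell cycle genes and -0.06 for 25 growth factors and vasoactive peptides. Fn1, which encodes fibronectin, differed by 0.21, Ccn2 by -0.37, Mcm5 by -0.77 and Ptn by -1.24, the last 2 above background on 4 of 4 AngII arrays and 2 of 4 AngII+CsA arrays. With normexp background correction the matrix and fibrosis list passed camera in both fits, at a median of 0.13 (adjusted p = 0.018 on the groups alone and 0.0216 with the block). Those calls used the preset correlation. Without normexp, the correlation estimated for this list was 0.15 (adjusted p = 0.838 by camera, and 0.721 with the block). The list did not pass there with the preset correlation either, so these values do not test the normexp calls. Metabolic and stress lists did not pass either, with medians of 0.05 for 17 calcium channels and pumps, 0.03 for 17 redox genes, -0.01 for 24 endoplasmic reticulum stress genes, 0.06 for 19 sterol synthesis genes and -0.06 for 19 glycolysis and hypoxia genes. The stress list turned to 0.12 and passed camera in both fits with normexp background correction (adjusted p = 0.018 and 0.0216), and the sterol list passed without AngII replicate 4 (median 0.24, adjusted p = 0.0396) and without AngII+CsA replicate 1 (median 0.20, adjusted p = 0.0274). These calls too used the preset correlation. With all arrays and without normexp, the correlation estimated for the sterol list was 0.551 (adjusted p = 0.865 by camera). For the stress list it was 0.285 (adjusted p = 0.949). Neither list passed there with the preset correlation, so these values do not test the calls. The median of 11 reference genes was 0.02.

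**Figure D4:**
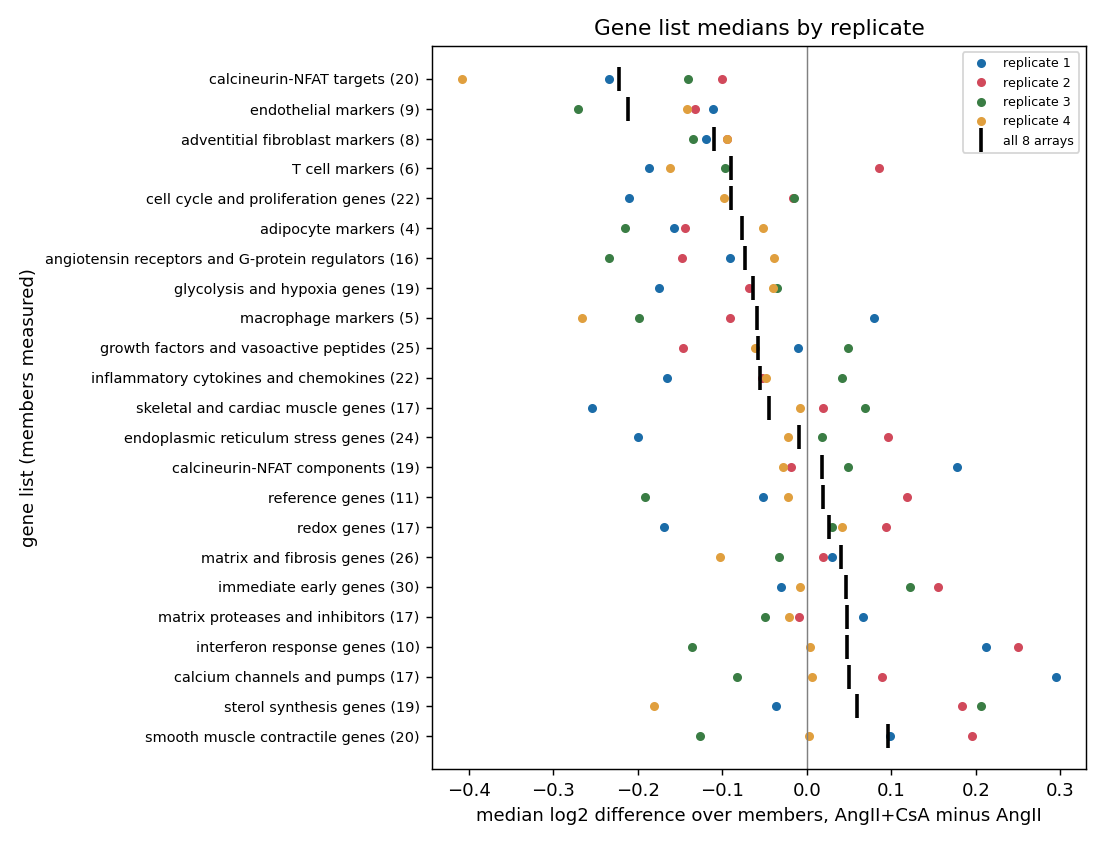
Median log2 difference between AngII+CsA and AngII over the measured members of each of the 23 gene lists, with the number measured in parentheses; points are the 4 replicate pairs and black ticks the medians over all 8 arrays. The calcineurin-NFAT targets lie lowest at -0.22, and the median of the smooth muscle contractile genes is the highest at 0.10.

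Lists of markers of other cells that an aortic culture could hold did not pass camera in either fit. Of 9 endothelial markers, 8 had negative differences, with a median of -0.21 (adjusted p = 0.247 by camera, 0.119 with the block). Their median level was -2.34 with AngII and -2.59 with AngII+CsA. The lowest signals above background lay between -4.03 and -3.03 over the arrays, so this shift is one of dim signals. That list did pass camera on the groups alone with normexp background correction (median -0.14, adjusted p = 0.0367) and with the block without replicate 1 (median -0.23, adjusted p = 0.0185). Both calls used the preset correlation. With all arrays and without normexp, the correlation estimated for the list was 0.0643 (adjusted p = 0.804 by camera) and -0.0923 with the block (adjusted p = 0.573). The list did not pass there with the preset correlation either, so these values do not test the 2 calls. Vwf differed by -0.32 and was above background on 4 of 4 AngII arrays and 3 of 4 AngII+CsA arrays. The medians were -0.11 for 8 adventitial fibroblast markers, -0.06 for 5 macrophage markers, -0.09 for 6 T cell markers and -0.04 for 17 skeletal and cardiac muscle genes. The 4 measured adipocyte markers had a median of -0.08 and were too few to test. The fry test, which asks only whether members move one way on balance, called the endothelial list with the block (adjusted p = 0.0392) and 0 lists on the groups alone. Its test for change in either direction called 5 lists with the block, namely the calcineurin-NFAT targets, endothelial markers, immediate early genes, matrix proteases and inhibitors, and inflammatory cytokines and chemokines, and 0 on the groups alone.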

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

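Of the tests in this part, the counts of splits for the groups alone, for the gene lists and for the calcineurin-NFAT targets and the alignment of the Serpinb1 probes were set before their results were seen; the tests of scaling, of the second Rcan1 probe, of the pair-parting splits and of the replicate 1 arrays were chosen after.

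Among 174 sets of 4 values (named genes, list medians and array measures within a group), 6 had an array far from the other 3 by Dixon's ratio, where chance gives about 8.7. Usp18 was at -0.84 in AngII replicate 3, with the other AngII arrays between -1.64 and -1.51. The prostacyclin receptor gene Ptgir was at -0.43 in AngII+CsA replicate 4, with the others between -0.55 and -0.54. Chac1, a stress-induced glutathione-degrading enzyme, was at 0.12 in AngII+CsA replicate 1, with the others between 2.89 and 3.41. Pfkfb3, a regulator of glycolysis, was at 4.09 in AngII+CsA replicate 3, with the others between 3.64 and 3.67. The skeletal myosin gene Myh2 was at -0.25 in AngII+CsA replicate 3, with the others between -1.98 and -1.79. The median level of the adventitial fibroblast markers was 5.40 in AngII+CsA replicate 1, with the others between 4.01 and 4.15.

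Rcan1 was lower with AngII+CsA in 4 of 4 pairs. Scaling is argued against as the cause, since the smallest fall under 3 other scalings was -2.25 and the median of all genes moved by at most 0.0258. A fault of a single probe is also argued against, because the second probe gave -1.51 (95% interval -1.95 to -1.06 with the block) and was lower in 4 of 4 pairs. On the groups alone, 35 of 35 splits of the 8 arrays gave at least the 0 genes of the real split, and the highest other split, which sets replicates 1 and 3 against 2 and 4, gave 2146, which points to the structure by replicate. Every split reaches a count of 0, so this comparison decides nothing. With the block, 1 of the 8 splits that part every pair, the real one, gave 4 genes and the highest of the others 0, and 8 splits are too few for a share under 0.05. For the calcineurin-NFAT targets 1 of 35 splits, the real one, gave a camera p as small (1.94e-05 against 0.00281 for the smallest other). With the block, 1 of the 8 splits that part every pair, again the real one, gave this list a p as small (2.92e-05 against 0.00913), and 8 splits are too few here as well, so chance under the pairing cannot be told apart from an effect of cyclosporin on the list. The call was also lost with an estimated correlation (adjusted p = 0.248, and 0.435 with the block). By number of lists, 24 of 35 splits called as many lists as the real 1 and up to 7. Most of the 35, the split with 7 lists among them, keep a pair on 1 side and so carry the structure by replicate. The other splits that part every pair called 0 or 1 list on the groups alone, and they are too few to decide.

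Serpinb1b and Serpinb1c were lower together with Serpinb1a. Their values may come in part from cross-hybridisation with Serpinb1a transcripts, because the other probe of each was above background on 1 and 0 of 8 arrays. The best ungapped alignments matched 36.7% of the Serpinb1b probe and 30% of the Serpinb1c probe to the Serpinb1a probe, but probes from different places of related transcripts need not match each other, so this and a fall of the paralogs themselves cannot be told apart without the transcript sequences. An effect of cyclosporin on Serpinb1a remains the biological explanation that the design offers, and it was tested only as the group difference.

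The arrays of replicate 1 differed from the other 6 by more than 2 log2 in 330 genes, 158 higher and 172 lower. Signals of single probes are argued against, since 68 of 83 other probes of these genes, 81.9% (exact 95% interval 72 to 89.5), differed the same way. Probe GC content accounted for 9.56% of the variance of the difference over genes, too little to be its whole cause. Replicate 1 lay on 1 slide of its own, so a difference of the cultures and an effect of the slide cannot be told apart. No biological explanation was tested, because the labels name no difference between the cultures.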

How the results depend on the processing

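The fits with the block under other settings, the random block, the list without Rcan1 and the omission of both replicate 1 arrays were chosen after seeing the data. On the groups alone 0 genes passed under every setting without a block; the replicate block, identical to the slide as a block, gave 4 genes and a random block for replicate 6, adding Nkd2 and Plekhs1. Rcan1 stayed lower throughout, at -2.26 with the replicate block and the random block, where it passed, between -2.57 and -2.03 when 1 array was left out, where it did not pass, and at -1.88 with the mean of its probes. At the main settings the block changed no call of a full list by camera with the preset correlation. Without Rcan1 the calcineurin-NFAT targets went from an adjusted p of 0.0626 to 0.0194 (0.594 and 0.573 with an estimated correlation). With normexp the endothelial list was called only without the block, and with no filter the immediate early list only with it. Lists past camera numbered 1 with the authors' table, other scalings and the stricter filter, and 1 with no filter on dim probes (interferon response genes), but 3 with normexp background correction (matrix and fibrosis, endoplasmic reticulum stress and endothelial), 0 with an estimated correlation, 0 by fry, and 0 to 2 when 1 array was left out (interferon response without AngII replicate 3, sterol synthesis without AngII replicate 4 or AngII+CsA replicate 1). With the replicate block, 4 genes passed, but 0 with no filter on dim probes (Rcan1 -2.26, adjusted p = 0.241 over 28785 genes, against a range of 0.000771 to 0.285 over the blocked settings), 2 with the authors' table (Rcan1 and Serpinb1c), 3 with normexp, where Serpinb1b at -0.84 (adjusted p = 0.0692) was lost and Serpinb1c became -1.02, 5 with the stricter filter (adding Nkd2), 3 with outlier spots kept (Serpinb1b, adjusted p = 0.0514), and 0 without any 1 pair, where fewer arrays remained and Rcan1 lay between -2.35 and -2.17. Lists with the block numbered 2 with normexp (matrix and fibrosis, endoplasmic reticulum stress), 2 with no filter (immediate early, interferon response), 0 with an estimated correlation, and 1 to 3 without 1 pair (endothelial markers and angiotensin receptors without replicate 1, interferon response without replicate 3). The endoplasmic reticulum stress list, at -0.01, became 0.12 under normexp with either fit, past the threshold. The calcineurin-NFAT targets stayed below 0 in all settings, between -0.41 and -0.07 without 1 array and between -0.36 and -0.14 otherwise, and were not called with normexp, with no filter or without AngII replicate 2 or AngII+CsA replicate 4. Without both replicate 1 arrays 0 genes passed and the list kept its call. The cause was not tested for these changes; with no filter more genes were tested, and the unadjusted p of Rcan1 with the block also went from 9.66e-07 to 1.68e-05. Signals near background limit the dim genes: 17101 of 41174 probes were above background on no array.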

Other observations

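The genes in this part were chosen after their values were seen; the adjusted p-values given are those of the fits over all genes tested.

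Arrays of different replicate numbers differed widely within a treatment, and the number is the same variable as the slide. Over the 4 replicate numbers 10120 of the 14881 genes differed past an adjusted p of 0.05 by limma with treatment in the model. Both arrays of replicate 1 were higher in the acute phase gene Saa3 (5.31 in log2 above the mean of the other 6), in the transcription factor gene Foxa2 (4.28) and in Epyc, which encodes the proteoglycan epiphycan (3.93). They were lower in the RNA-binding protein gene Khdrbs3 (-4.07), in the transglutaminase gene Tgm2 (-3.12) and in Tnnt2, which encodes cardiac troponin T (-3.34). These 6 genes were above background on all 8 arrays. By list, the median difference of replicate 1 from the others was -0.85 for smooth muscle contractile genes, -0.70 for sterol synthesis genes, -0.61 for immediate early genes, -0.59 for the calcineurin-NFAT targets and 0.57 for inflammatory cytokines and chemokines.

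Besides the genes named in the comparison, the 4 largest negative differences among genes with a symbol and an unadjusted p under 0.05 with the block were those of the steroid dehydrogenase gene Akr1c18 (-1.64), the hormone gene Fgf21 (-1.44), the T cell receptor gamma locus Tcrg (-1.35) and Stc1, which encodes stanniocalcin 1 (-1.31), each lower in 4 of 4 pairs. By the same rule the 3 largest positive ones were those of Ercc6l2, a helicase-like gene (0.80), Lysmd3 (0.71) and Chrdl2, which encodes a chordin-like antagonist of bone morphogenetic proteins (0.70), each higher in 4 of 4 pairs. None of the 7 passed either fit, with an adjusted p by limma with the block of 0.603 for Stc1, 0.647 for Chrdl2 and 0.885 for the others. Dpf3, a chromatin remodelling subunit, differed by -1.04 with an adjusted p of 0.0747. Fgf21, Tcrg and Dpf3 were above background on 3 of 4 AngII arrays and 1 of 4 AngII+CsA arrays, Akr1c18 on 3 and 2 and Lysmd3 on 3 and 4, so these sizes are uncertain. The 6 measured Serpinb genes outside the Serpinb1 group differed by -0.02 (Serpinb6a), 0.06 (Serpinb6c), -0.28 (Serpinb6b), -0.10 (Serpinb2), -0.32 (Serpinb3c) and -0.09 (Serpinb9e), and none passed either fit. In all, 1509 genes were lower and 711 higher in 4 of 4 pairs, 14.9% of genes where chance gives 12.5%. No spread was computed for the 12.5%. The median of all genes was -0.0259 with the main scaling and -0.00448 with quantile normalization. Whether the excess of lower genes depends on the scaling was not tested.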
